A study of Mus musculus with 6 samples.

How the data were processed

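The samples were 6 libraries of primary mouse muscle stem cells cultured for 2 days, 3 without and 3 with 11,12-EET; the dose and the control medium are not given in the sources used here. Per the labels' protocols, poly(A) RNA was selected from total RNA, fragmented, made into libraries with a dUTP-marked second strand and sequenced as paired reads. The deposited table holds whole-number counts per gene symbol and library, which were not normalized. FastQC, cutadapt and DESeq2 and the genome build GRCm38 are named, per the submitters' processing notes; the aligner, the counting tool, its strand setting and the annotation release are not given in the sources used here. The table has 55494 rows, of which 25226 had no count in any library. Low counts were even more often than odd (61.7 ± 0.388% of counts of 11 to 50 were even in controls and 65.3 ± 0.331% with EET, n = 3 each), so both mates of a fragment were probably counted apart for many genes. Precision is therefore lower than the totals of 30371291 to 37243882 counts would give, and a fit on counts divided by 2 was added. Groups and replicate numbers were taken from the sample titles.

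Counts were analysed in R 4.3.3 with edgeR 4.0.16 (filterByExpr, TMM scaling, estimateDisp and glmQLFit with robust estimation, glmQLFTest), comparing 3 EET with 3 control libraries without a block. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, and rose, fell, higher and lower are used of called genes; 16097 genes passed the filter. CPM values are TMM scaled and errors of log2 fold changes are standard errors of the edgeR fit. Shares of counts were compared with exact two-sided permutation tests of the difference of means, whose smallest p is 0.1 for 3 against 3.

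Gene lists were tested with camera in limma 3.58.1, with a preset correlation between genes of 0.01, adjusted over 28 lists fixed before the data were examined. Camera called 8 lists, and 0 with the correlation estimated per list, where the lowest adjusted p was 0.422; fry, which asks whether the genes of a list move 1 way on balance and not whether they stand apart from other genes, called 15. The lists hold 627 members, of which 20 were matched through older symbols. A list of 88 cytosolic ribosomal protein genes and the list of aryl hydrocarbon receptor targets were chosen after the data were seen.

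The named genes were chosen by a rule fixed before the data were examined. It takes the 8 higher and the 8 lower genes with the smallest p among those with an adjusted p under 0.05, an absolute log2 fold change of at least 1, a mean of at least 2 CPM and no overlap between the groups, leaving out predicted gene models. It adds the 2 measured members with the smallest p in each list and 13 genes fixed by name (Pax7, Myf5, Myod1, Myog, Mki67, Cdkn1a, Nqo1, Hmox1, Sod2, Ephx1, Ephx2, Il6 and Angptl4). Of the genes this rule selects, 3 are not reported here.

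Coordinates, mRNA lengths and GC content come from GENCODE M21 on GRCm38, with 53591 rows matched by symbol; mRNA length is that of the longest protein-coding transcript. This measure replaced the median over transcripts after it was seen to follow the fold changes more closely. The length and GC trend was removed by a robust loess (span 0.3) of each library's deviation from the mean of all 6 on log2 length and GC percent, fitted on protein-coding genes and entered as an offset in edgeR. List medians were also set among 10000 random lists matched on mRNA length (20 bins) and expression (5 bins).

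The pipeline was tested on simulated counts for the comparison of EET with control. They were drawn from the means of the 16097 genes that passed the filter, with 200 changed. After the simulated counts were filtered in turn, 15691 to 15744 genes were tested. Without a trend the pipeline recovered 58.2% of genes changed 1.5-fold, 60% changed 2-fold and 95.4% changed 4-fold. Of its 147 calls 7 were of unchanged genes. With the observed length and GC trend added, 6025 of 6181 calls were of unchanged genes, and after its removal 9 of 151 were. The added trend was the same kind of smooth as the one removed. The simulation therefore cannot show what share of the calls in the corrected fit of the real libraries is false. Alternatives were RLE scaling, library totals, no filter, a filter of over 5 CPM in at least 3 libraries, DESeq2 1.42.0, limma-voom, glmQLFit without robust estimation, the replicate number as a block, leaving out each library, and for lists an estimated correlation and fry. Added after the data were seen were the fit with the length and GC trend removed, counts divided by 2, a fit without control 1 and EET 3, and a fit without the row of the rRNA gene CT010467.1, which held 1.19 ± 0.316% of counts in controls and 0.893 ± 0.0278% with EET.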

Results

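Bulk RNA sequencing was used to ask how 11,12-EET changes the transcriptome of muscle stem cells, the Pax7-positive cells that repair adult skeletal muscle. EET stands for epoxyeicosatrienoic acid, a lipid mediator that cytochrome P450 enzymes make from arachidonic acid and that soluble epoxide hydrolase, the product of Ephx2, breaks down. Primary muscle stem cells of wild-type mice were cultured for 2 days with or without 11,12-EET, and 3 control and 3 EET libraries were made from poly(A) RNA. Library totals ran from 30371291 to 37243882 counts, and those of the groups overlapped (difference of means −1148180 counts, exact two-sided permutation p = 0.8, where 3 against 3 libraries cannot give a p below 0.1). The labels do not say that libraries of a group came from separate animals or cultures, so p-values measure only the spread between these libraries, which may be technical. No pair of libraries held the same counts within sampling noise (lowest chi-square per gene of any pair, 5.92).

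Short mRNAs were higher and long mRNAs lower in the EET libraries. Of 37 respiratory chain genes 33 rose and 0 fell, or 19 and 1 after a correction for mRNA length and GC content. Of 20 genes of antioxidant enzymes 18 rose and 1 fell, or 10 and 3 after the correction. Cyp1a1, a cytochrome P450 induced through the aryl hydrocarbon receptor, rose from 4.68 ± 0.351 to 19.6 ± 3.2 CPM (counts scaled by library total and TMM factor; mean ± SD, n = 3 each), and Angptl4, a target of the PPAR fatty acid receptors, rose from 39.8 ± 2.41 to 75.9 ± 1.95 CPM. Of 27 extracellular matrix genes 21 fell and 2 rose, or 17 and 1 after the correction. Fn1, 1 of them, fell from 905 ± 99.8 to 422 ± 48.7 CPM (log2 fold change −1.10, or −0.46 corrected), and the collagen gene Col6a3, outside that list, from 223 ± 11.8 to 83.9 ± 9.72 CPM (−1.41, or −0.75 corrected). Pax7, the transcription factor that marks muscle stem cells, fell from 114 ± 4.71 to 83.5 ± 1.64 CPM, a call that was lost after that correction (log2 fold change −0.0045, adjusted p = 0.96). Of 27 genes of muscle differentiation 15 rose, most of them from a low level, and 3 fell, or 10 and 0 after the correction. Under a filter of over 5 CPM in at least 3 libraries their list was not called (camera adjusted p = 0.929).

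Of 16097 genes tested, 3967 were higher and 3749 lower with EET (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), of which 702 were at least 2-fold higher and 399 at least 2-fold lower. The 3 EET libraries lay wholly above or below the 3 controls for 9282 genes (57.7%), where chance gives 10%. Measured over 13930 protein-coding genes, the log2 fold change correlated with mRNA length (length of the longest protein-coding transcript) at a Spearman rho of −0.68, across genes, which are not independent replicates. The median log2 fold change was 1.07 for 269 mRNAs under 750 bp, of which 180 rose and 1 fell, and −0.70 for 537 mRNAs of 9000 bp and over, of which 12 rose and 391 fell. Genes called higher had a median length of 1792 bp and genes called lower 5379 bp. Each library's deviation from the mean of all 6 changed with length, by 0.12, 0.23 and 0.24 log2 units per doubling in the controls and by −0.27, −0.21 and −0.11 in the EET libraries. After removal of each library's trend with mRNA length and GC content, a correction chosen after the data were seen, 2863 genes were higher and 2329 lower, and 153 were at least 2-fold higher and 513 at least 2-fold lower. In both fits 1829 genes were higher and 1461 lower, and 314 called genes had opposite directions. List medians with this trend removed are given beside each gene group. Values with the trend removed are relative to mRNAs of like length and GC content. A gene can therefore be called higher or lower there while its CPM hardly changed or moved the other way.

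**Figure D1:**
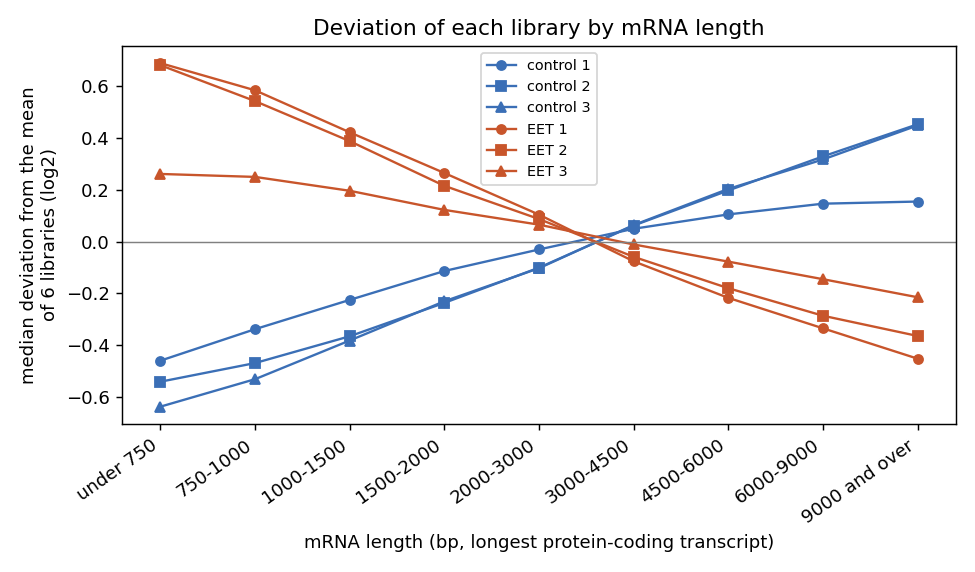
Median deviation of each library from the mean of 6 libraries (vertical axis, log2 units) for protein-coding genes in 9 classes of mRNA length (horizontal axis, bp); each line is 1 library, blue for control and orange for EET. All 3 EET lines fall with length and all 3 control lines rise, with control 1 and EET 3 the flattest of their groups (0.12 and −0.11 log2 units per doubling of length).

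Among the genes with the smallest p that were at least 2-fold higher, Chchd1, which encodes a mitochondrial ribosomal protein, rose by 2.01 ± 0.12 (log2 ± SE, adjusted p = 3.92e-07). Rplp1, Rplp0 and Rpl14, which encode cytosolic ribosomal proteins, rose by 1.80 ± 0.10, 1.24 ± 0.08 and 1.37 ± 0.09. Ribosomal protein genes have many processed pseudogenes that could share their reads, so their levels are uncertain. Hint1 rose by 1.57 ± 0.10, Polr1d, a subunit of RNA polymerases I and III, by 1.18 ± 0.08 and Rnf7, a ubiquitin ligase component, by 1.12 ± 0.07. These 7 mRNAs ran from 499 to 1358 bp, and with the length and GC trend removed each was still called higher, by 0.45 (Hint1) to 0.89 (Chchd1). Cyp1a1, at 57687928 to 57703824 on the plus strand of chromosome 9 (GRCm38), has an mRNA of 2697 bp and rose by 2.07 ± 0.14 (adjusted p = 5.15e-07), or 2.02 ± 0.13 with the trend removed.

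The genes with the smallest p among those at least 2-fold lower included genes of matrix, junction and receptor proteins. Col6a3, a collagen VI chain gene at 90765923 to 90843971 on the minus strand of chromosome 1, fell by 1.41 on the log2 scale (SE 0.08, adjusted p = 3.92e-07). Dsp, which encodes the desmosomal protein desmoplakin, had a log2 fold change of −1.86 ± 0.14, Akap12, a scaffold for protein kinase A, −1.32 ± 0.09 and Col15a1, a basement membrane collagen, −1.38 ± 0.12. Flt1 and Kdr, the VEGF receptors, had −1.16 ± 0.10 and −1.18 ± 0.11, and Fn1, the gene of fibronectin, −1.10 ± 0.09. Flt1 and Kdr are also markers of endothelial cells and Col15a1 of fibro-adipogenic cells, so a change in the share of other cells could give such falls. The mRNAs of these 7 genes ran from 5172 bp (Col15a1) to 10106 bp (Col6a3). All 7 were still called lower with the trend removed, from −0.46 (Fn1) to −1.22 (Dsp). An unstranded count would also take reads of antisense genes whose exons overlap Chchd1, Dsp, Col15a1 and Fn1, and of the genes named further on Ttn, Gins2, Pfkp, Psph, Col5a1, Pdgfra, Csf1r, Alas2 and Cdkn1a, and the strand setting of the counting is not given in the sources used here.

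**Figure D2:**
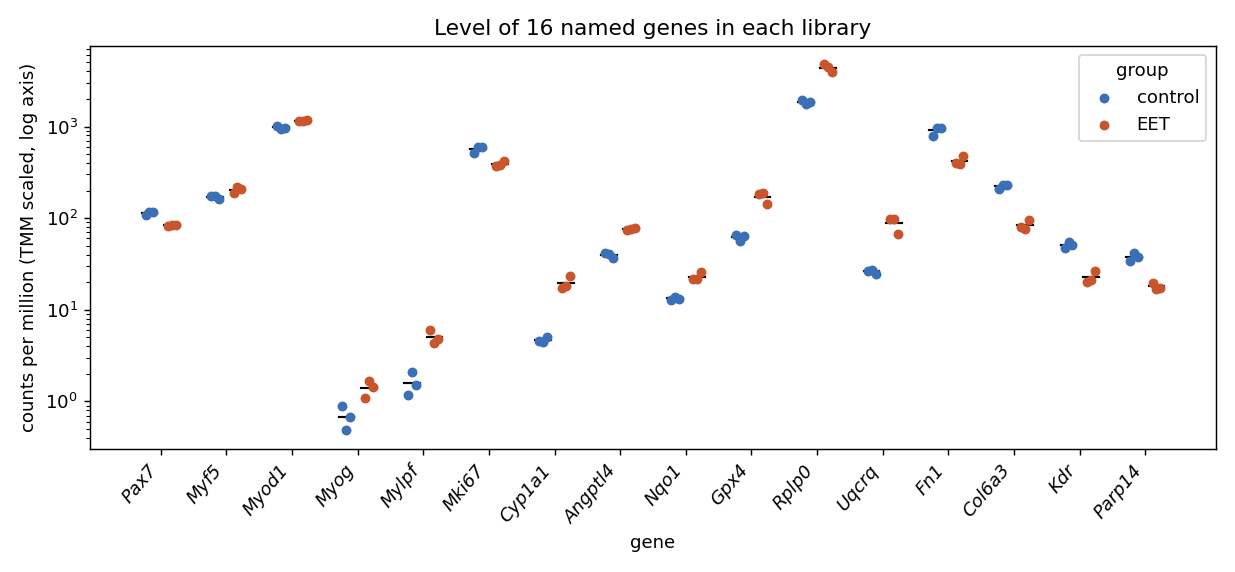
Level of 16 named genes in each library (vertical axis, CPM, log axis); blue points are the 3 control and orange points the 3 EET libraries, and black lines are group means. The groups do not overlap for any of the 16, with Cyp1a1 at 4.68 against 19.6 CPM and Fn1 at 905 against 422 CPM. Several of the genes drawn were selected by a rule that required no overlap, and 57.7% of all tested genes did not overlap. Named genes not drawn here, such as Hmox1, Ephx1 and Ephx2, did overlap.

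Genes of stem cell identity moved both ways. Of 23 measured members of the satellite cell identity and quiescence list, 8 rose, 5 fell and 10 did not pass, with the same counts adjusted over the list alone, and the list was not called (camera adjusted p = 0.757). With the trend removed 5 rose and 1 fell, at a median of 0.09. Pax7 fell by 0.45 on the log2 scale (SE 0.07, adjusted p = 6.34e-05), and Megf10, a receptor found on satellite cells, had −0.64 ± 0.09. Myf5 and Myod1, the myogenic determination factors, rose by 0.26 ± 0.07 (adjusted p = 0.0078) and 0.25 ± 0.06 (adjusted p = 0.0047). Tnfrsf12a, the TWEAK receptor, rose by 0.85 ± 0.08. Their mRNAs are long where the gene fell (5854 bp for Pax7, 7514 bp for Megf10) and short where it rose (984 bp for Tnfrsf12a), and with the length and GC trend removed none of these 5 was called: Pax7 was at −0.0045, Megf10 at −0.06, Myf5 at −0.0031, Myod1 at −0.11 and Tnfrsf12a at 0.04. The call of Myf5 was also lost without control replicate 3 (adjusted p = 0.0561) and without EET replicate 2 (adjusted p = 0.0564).

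Genes of differentiating muscle rose as a list. In the myogenic differentiation and sarcomere list, 15 of 27 measured members rose and 3 fell, or 16 and 3 adjusted over the list alone, with a median log2 fold change of 0.65 and a camera adjusted p of 0.0177 (adjusted p = 0.422 with an estimated correlation). Mylpf, a fast-muscle myosin light chain, rose from 1.6 ± 0.475 to 5.05 ± 0.864 CPM, while Ttn, the gene of titin, had a log2 fold change of −0.80 ± 0.13. Myog, the factor that starts terminal differentiation, rose by 1.02 ± 0.36 (adjusted p = 0.0278) at about 1 CPM, from 0.681 ± 0.206 to 1.39 ± 0.292. That call was lost without control replicate 2 (adjusted p = 0.113), control replicate 3 (0.068), EET replicate 2 (0.104) or EET replicate 3 (0.0512). The members had a median mRNA length of 1495 bp, and with the trend removed 10 rose and 0 fell, with a list median of 0.44 (adjusted p = 0.0208; adjusted p = 0.299 with an estimated correlation). Mylpf was then at 0.67 and still called, and Myog at 0.55 was not (adjusted p = 0.274). Ttn, whose longest mRNA is 106824 bp, was then called higher at 0.57, although its level fell from 50.8 ± 9.86 to 29.1 ± 2.55 CPM. At such an extreme length that value depends on the fitted trend. Under a filter of over 5 CPM in at least 3 libraries, which removes the weakly expressed members, the list was no longer called (median 0.08, adjusted p = 0.929).

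The cell cycle lists were not called by camera in the main fit. In the DNA replication and G1/S list 14 of 30 members rose and 4 fell, also adjusted over the list alone, with a median of 0.14 (camera adjusted p = 0.0877; 0.0485 without control replicate 1). Gins2, a subunit of the replicative helicase, rose by 1.02 ± 0.10 and Pcna, the sliding clamp, by 0.71 ± 0.07. With the trend removed 9 rose and 3 fell and the list was called higher, at a median of 0.08 (adjusted p = 0.0394; adjusted p = 0.378 with an estimated correlation), Gins2 being at 1.22 and Pcna at 0.24. Of 30 genes of G2 and mitosis, 11 rose and 13 fell, also adjusted over the list alone. Trend removal left 7 higher and 8 lower (median −0.006). Birc5 and Cenpa, which act at the centromere, rose by 1.00 ± 0.09 and 0.92 ± 0.08 (1.09 and 0.43 with the trend removed), whereas Mki67, the gene of the Ki-67 proliferation antigen, had −0.53 ± 0.08. Mki67 has an mRNA of 10061 bp, and its direction turned with the trend removed (0.11, adjusted p = 0.041). Cdkn1a, which encodes the cell cycle inhibitor p21, was at 318 ± 6.3 CPM in controls and 349 ± 12.1 CPM with EET (adjusted p = 0.099; called higher with the replicate block, 0.13, adjusted p = 0.0428), and its log2 fold change of 0.13 turned to −0.11 with the trend removed (adjusted p = 0.0541). Among 12 measured replication-dependent histone genes 5 rose and 1 fell, also adjusted over the list alone, with H4c9 at 1.21 ± 0.14 and H3c3 at 1.13 ± 0.26. These lost their calls with the trend removed (0.20 and −0.0055), where 0 members rose, 2 fell and the median was 0.002. Histone mRNAs mostly lack a poly(A) tail and share near-identical sequence, so their levels are uncertain.

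Antioxidant enzymes were higher as counted. Of 20 peroxide and superoxide scavenging enzymes, 18 rose and 1 fell, also adjusted over the list alone, with a median of 0.67 (camera adjusted p = 2.1e-06; adjusted p = 0.492 with an estimated correlation). Gpx1 and Gpx4, glutathione peroxidases, rose by 1.24 ± 0.09 and 1.46 ± 0.10, and Sod2, the mitochondrial superoxide dismutase, by 0.35 ± 0.07. Among random lists matched on mRNA length and expression, the median of the scavenging enzymes lay at percentile 94.38. It was inside the central random range of 0.35 to 0.70, so this test did not set the list apart from its length. The list's median mRNA length was 1536 bp; with the trend removed 10 members rose and 3 fell, at a median of 0.25 (adjusted p = 0.00189; adjusted p = 0.299 with an estimated correlation), and Gpx1, Gpx4 and Sod2 were still called at 0.49, 0.64 and 0.75. In the list of NRF2 target genes 14 of 28 rose and 4 fell, also adjusted over the list alone, with a median of 0.19 (camera adjusted p = 0.0435; adjusted p = 0.643 with an estimated correlation). Prdx1 and Txn1, a peroxiredoxin and a thioredoxin, rose by 0.86 ± 0.08 and 1.12 ± 0.11, and Nqo1, a quinone reductase, by 0.79 ± 0.11, while Hmox1, heme oxygenase 1, was at 361 ± 13.3 and 352 ± 18.6 CPM (adjusted p = 0.694). Members of this list had a median length of 1997 bp. With the trend removed 6 rose and 6 fell, the median was −0.03 and the call was lost (adjusted p = 0.695). Prdx1 was then at 0.67, Txn1 at 0.37, Nqo1 at 0.35 (adjusted p = 0.02) and Hmox1 called lower at −0.49. Among matched random lists the NRF2 median as counted lay at percentile 2.37, below their median of 0.35. The NRF2 call was also lost without control replicate 2 (adjusted p = 0.0643), control replicate 3 (0.0808) or EET replicate 1 (0.0687), with library totals as the scaling (0.0759), under the filter of over 5 CPM (0.0714) and with counts divided by 2 (0.0515).

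Respiratory chain genes of the nucleus rose together. Of 37 members 33 rose and 0 fell, or 34 and 0 adjusted over the list alone, with a median of 0.97 (camera adjusted p = 1.27e-11; adjusted p = 0.512 with an estimated correlation). Uqcrq, a subunit of complex III, rose from 26.2 ± 1.26 to 87.5 ± 17 CPM, and Ndufa4 rose by 1.34 ± 0.10; with the trend removed Uqcrq went from 1.74 to 1.26 and Ndufa4 to 0.24. The members are short, at a median of 1187 bp, and with the trend removed 19 rose and 1 fell, at a median of 0.18 (adjusted p = 5.9e-05; adjusted p = 0.299 with an estimated correlation). Of 12 mRNAs encoded by the mitochondrial genome 9 rose and 0 fell, also adjusted over the list alone, at a median of 0.52 (camera adjusted p = 0.00204; adjusted p = 0.422 with an estimated correlation). Of these, mt-Nd6 rose by 0.88 ± 0.07 and mt-Nd1 by 0.53 ± 0.06; reads of mt-Nd6 and mt-Nd5 could be mixed, since the genes overlap on opposite strands. This list turned with the trend removed, to a median of −0.24 with 0 members higher and 3 lower (adjusted p = 0.0208; adjusted p = 0.378 with an estimated correlation), mt-Nd6 and mt-Nd1 both being at −0.24. The share of counts from mitochondrially encoded genes was 1.33 ± 0.0688% in controls and 1.64 ± 0.0687% with EET (n = 3 each, exact permutation p = 0.1, the smallest possible).

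**Figure D3:**
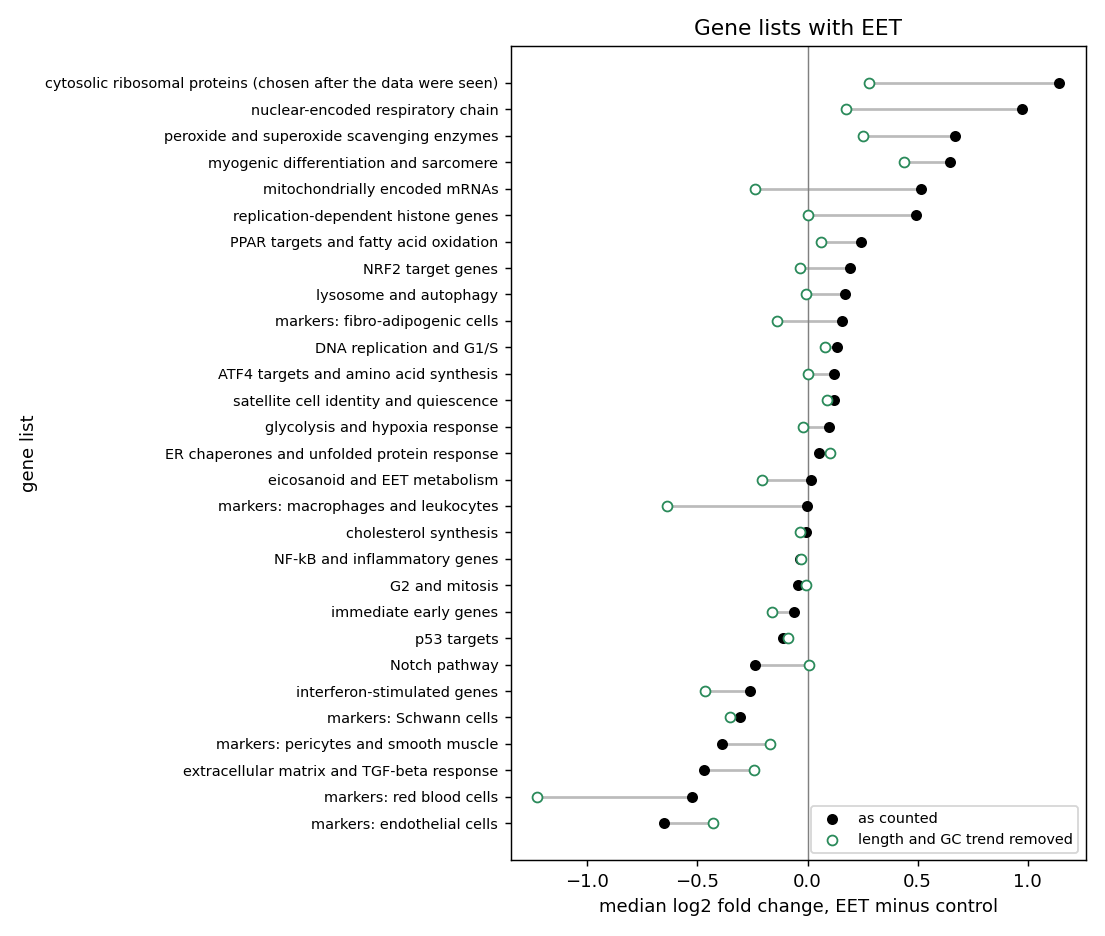
Median log2 fold change of the measured members of each gene list (horizontal axis, EET minus control) for the 28 lists fixed before the data were examined and the ribosomal protein list chosen after; filled points are values as counted and open points values with the length and GC trend removed. The respiratory chain moves from 0.97 to 0.18 and the mitochondrially encoded mRNAs from 0.52 to −0.24.

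Matrix genes fell. In the extracellular matrix and TGF-beta response list, 21 of 27 members fell and 2 rose, also adjusted over the list alone, with a median log2 fold change of −0.47 (camera adjusted p = 4.25e-05; adjusted p = 0.492 with an estimated correlation). Besides Fn1, Col5a1, a fibrillar collagen chain, fell from 151 ± 1.13 to 87.1 ± 6.68 CPM (log2 fold change −0.80, or −0.18 with the trend removed). The median length was 4722 bp, and with the trend removed 17 fell and 1 rose, at a median of −0.24 (adjusted p = 3.47e-05; adjusted p = 0.299 with an estimated correlation). Of 14 Notch pathway genes 2 rose and 6 fell, also adjusted over the list alone, and the list was not called (median −0.24, camera adjusted p = 0.304). Its counts were 2 higher and 2 lower with the trend removed, at a median of 0.005. Jag1, a Notch ligand, had −0.97 ± 0.09 and Hes6, a HES family regulator, rose by 0.89 ± 0.09; both kept their calls with the trend removed (−0.53 and 0.28).

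Interferon-stimulated genes were lower as a list, though most members did not pass. Of 28 members 10 fell and 2 rose, also adjusted over the list alone, with a median of −0.26 (camera adjusted p = 0.0197; adjusted p = 0.643 with an estimated correlation). Parp14 had −1.07 ± 0.10 and Ddx58, which encodes the RNA sensor RIG-I, −0.74 ± 0.09 (−0.50 and −0.55 with the trend removed). For the list, removal of the trend increased the difference: at a median length of 2557 bp, 18 members fell and 1 rose, with a median of −0.47 (adjusted p = 1.28e-06; adjusted p = 0.299 with an estimated correlation). The call as counted was lost without EET replicate 3 (adjusted p = 0.0869), without control 1 and EET 3 together (0.119) and under the filter of over 5 CPM (0.0539). Of 24 NF-kB and inflammatory genes 10 rose and 8 fell, also adjusted over the list alone (camera adjusted p = 0.914). Of these, 3 rose and 8 fell with the trend removed (median −0.03). The chemokine genes Cxcl1 and Ccl7 rose by 0.66 ± 0.07 and 0.75 ± 0.09, and the cytokine gene Il6 rose from 15.4 ± 0.545 to 20.5 ± 1.96 CPM (adjusted p = 0.00377). These are short mRNAs (953 bp for Cxcl1, 801 bp for Ccl7), and with the trend removed Cxcl1 was at −0.14 (adjusted p = 0.0762), Ccl7 was called lower at −0.17 and Il6 was at 0.21 (adjusted p = 0.0725).

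Lipid genes showed a few large changes without a shift of the lists. In the eicosanoid and EET metabolism list 4 of 21 members rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.757). Trend removal left 4 higher and 3 lower, at a median of −0.21. Cyp1a1 led this list, followed by Fabp5, a fatty acid binding protein, at 0.81 ± 0.10 (0.02 with the trend removed, where it was not called). The epoxide hydrolase genes did not pass the test: Ephx1 was at 31.2 ± 1.65 and 33.2 ± 3.48 CPM (adjusted p = 0.479) and Ephx2 at 0.621 ± 0.331 and 0.64 ± 0.45 CPM (adjusted p = 0.977), a level too low to show a moderate change. With the trend removed Ephx1 was called lower at −0.28. Of 26 PPAR targets and fatty acid oxidation genes 12 rose and 3 fell, also adjusted over the list alone, with a median of 0.24 (camera adjusted p = 0.0616; 0.0272 without control replicate 1). Trend removal left 10 higher and 3 lower, at a median of 0.06. Angptl4, at 33773750 to 33781830 on the minus strand of chromosome 17, rose by 0.93 ± 0.08 (adjusted p = 1.1e-06), and Eci1, an enzyme of fatty acid oxidation, by 0.99 ± 0.11. Angptl4 has an mRNA of 3308 bp and was at 1.02 ± 0.06 with the trend removed, against 0.28 for Eci1. In the cholesterol synthesis list 4 of 25 rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.788), against 6 and 5 with the trend removed (median −0.03).

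The remaining pathway lists were not called by camera as counted. Glycolysis and hypoxia response genes rose in 9 and fell in 8 of 26 cases, also adjusted over the list alone (adjusted p = 0.914), and Hk2 and Pfkp, which act early in glycolysis, had −0.51 ± 0.07 and −0.41 ± 0.08. After trend removal 6 rose and 6 fell (median −0.02), Hk2 lost its call (−0.09, adjusted p = 0.174) and Pfkp was at −0.17. Of 22 p53 targets 3 rose and 5 fell, also adjusted over the list alone (adjusted p = 0.749), with the apoptosis gene Bax at 1.10 ± 0.12 and the polymerase gene Polk at −0.60 ± 0.10. Trend removal left 4 higher and 6 lower (median −0.09), with Bax at 0.31 and Polk at −0.39. ATF4 targets and amino acid synthesis genes rose in 10 and fell in 5 of 24 cases, also adjusted over the list alone (adjusted p = 0.519), with Atf4 at 0.62 ± 0.07 and Psph, of serine synthesis, at 0.75 ± 0.10. Trend removal left 5 higher and 2 lower (median 0.002), with Atf4 at 0.24 and Psph at 0.38. Among 20 ER chaperones and unfolded protein response genes 8 rose and 5 fell, or 8 and 6 adjusted over the list alone (adjusted p = 0.746), with Sec61b, of the translocon, at 1.40 ± 0.12 and Sel1l, of ER-associated degradation, at −0.74 ± 0.08. After trend removal 10 rose and 5 fell (median 0.10), with Sec61b at 0.20 and Sel1l at −0.24. Lysosome and autophagy genes rose in 12 and fell in 3 of 28 cases, or 15 and 3 adjusted over the list alone (adjusted p = 0.106), with the autophagosome genes Gabarapl2 at 0.72 ± 0.09 and Map1lc3a at 0.85 ± 0.11. After trend removal 7 rose and 5 fell (median −0.009), Gabarapl2 was at 0.33 and Map1lc3a lost its call (0.08, adjusted p = 0.559). Of 21 immediate early genes 7 rose and 9 fell, or 8 and 9 adjusted over the list alone (adjusted p = 0.752), with Ier2 at 0.53 ± 0.09 and Fosb at −0.85 ± 0.17. With the trend removed the immediate early list was called lower, with 2 higher, 10 lower and a median of −0.16 (adjusted p = 0.0103; adjusted p = 0.299 with an estimated correlation). Fosb was at −0.69, and Ier2 lost its call (0.009, adjusted p = 0.923).

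Markers of other cell types that a muscle stem cell isolate can hold were measured, and those of endothelial cells fell. In controls Ngfr was at 187 CPM, Pdgfrb at 92.5 CPM, Pdgfra at 78.9 CPM and Kdr at 50.9 CPM. Other markers were lower, such as Csf1r at 19.8 CPM and Ptprc at 14.0 CPM. Of the myogenic genes, Pax7 was at 114 CPM and Myod1 at 977 CPM. The level of a single marker does not give a share of cells. Of 16 endothelial markers 11 fell and 1 rose, also adjusted over the list alone, with a median of −0.65 (camera adjusted p = 0.0016; adjusted p = 0.422 with an estimated correlation), and 11 fell and 0 rose with the trend removed, at a median of −0.43 (adjusted p = 2.62e-05; adjusted p = 0.299 with an estimated correlation). Their summed share of counts was 0.0406 ± 0.000748% in controls and 0.025 ± 0.00128% with EET (n = 3 each, exact permutation p = 0.1), and the groups were also apart for the markers of pericytes and smooth muscle (0.0277 ± 0.00138% and 0.0178 ± 0.000971%) and of Schwann cells (0.0492 ± 0.000712% and 0.0365 ± 0.00258%; exact permutation p = 0.1 for each). They overlapped for the markers of fibro-adipogenic cells (0.077 ± 0.00254% in controls and 0.0803 ± 0.00283% with EET, exact permutation p = 0.2) and of macrophages and leukocytes (0.0453 ± 0.00215% and 0.0369 ± 0.012%, exact permutation p = 0.4). The other marker lists were not called as counted. Of 11 markers of pericytes and smooth muscle 6 fell and 1 rose (adjusted p = 0.0965), with Pdgfrb at −0.64 ± 0.07 and Cspg4 at −0.82 ± 0.10, and of 10 Schwann cell markers 7 fell and 1 rose (adjusted p = 0.0965), with Ngfr at −0.51 ± 0.07 and Erbb3 at −0.74 ± 0.12. With the trend removed 4 pericyte and smooth muscle markers fell and 0 rose (median −0.17), and 6 Schwann cell markers fell and 0 rose (median −0.35). Pdgfrb, Cspg4, Ngfr and Erbb3 were still called, at −0.23, −0.21, −0.44 and −0.27. Among 18 macrophage and leukocyte markers 0 rose and 2 fell, namely Ptprc at −0.98 ± 0.15 and Csf1r at −0.58 ± 0.13. Their list was not called as counted (camera adjusted p = 0.667) but was without EET replicate 1 (camera adjusted p = 0.033). Trend removal changed this list: 10 fell and 1 rose, at a median of −0.64 (adjusted p = 0.000289; adjusted p = 0.379 with an estimated correlation). Ptprc was then at −0.64, and Csf1r lost its call (−0.26, adjusted p = 0.0976). In these 3 lists the counts adjusted over the list alone were the same. Of 17 markers of fibro-adipogenic cells 3 rose and 2 fell, or 2 and 2 adjusted over the list alone (adjusted p = 0.788), with Col15a1 and Pdgfra (−0.58 ± 0.08) the lower pair. After trend removal 1 rose and 5 fell (median −0.14), and Pdgfra lost its call (−0.035, adjusted p = 0.67). None of 4 red blood cell genes passed, over all genes or adjusted over the list alone (adjusted p = 0.978), nor with the trend removed (median −1.23). Hbb-bt was at 1.51 ± 2.36 and 1.05 ± 0.86 CPM and Alas2 at 0.843 ± 0.774 and 0.489 ± 0.332 CPM, and the level in controls came mostly from control replicate 1, without which Hbb-bt was called higher with EET (log2 fold change 2.82, adjusted p = 0.0254).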

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

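Of the settings below, the fits with the length and GC trend removed, with counts divided by 2 and without control 1 and EET 3 were chosen after the result was seen. Counts of called genes stayed within 1.5 times their values under RLE scaling, library totals, no filter, DESeq2, limma-voom, glmQLFit without robust estimation and counts divided by 2, and DESeq2 shared 7544 calls in the same direction. Leaving out each library gave 3291 to 4121 genes higher, 3029 to 3934 lower, 552 to 948 at least 2-fold higher, 281 to 555 at least 2-fold lower and 7 to 10 lists. Under the filter of over 5 CPM, 443 genes were at least 2-fold higher and 157 at least 2-fold lower; fewer genes were tested. With the length and GC trend removed, 2329 genes were lower and 153 at least 2-fold higher, while 513 were at least 2-fold lower. Without control 1 and EET 3 together, 759 genes were at least 2-fold lower; the cause was not tested. Without a filter, the lists of G1/S (adjusted p = 0.0161), PPAR targets (0.0219), lysosome (0.0396) and histone genes (0.0181) were called in addition; the filter of over 5 CPM called the pericyte markers (0.00982), counts divided by 2 the histone genes (0.0218), and the fit without control 1 and EET 3 the PPAR targets (0.0407) and Cdkn1a (0.0118). Camera with an estimated correlation called 0 lists and fry 15. Library totals moved the share of calls that were higher from 51.4% to 44%, and no scaling moved the median of all genes by over 0.1.

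With the length and GC trend removed, Ttn (0.57), Cxcl1 (−0.14), Ccl7 (−0.17), mt-Nd6 (−0.24), mt-Nd1 (−0.24), H3c3 (−0.0055), Myf5 (−0.0031), Myod1 (−0.11), Mki67 (0.11), Cdkn1a (−0.11), Ephx1 (−0.28), Ephx2 (−0.21), the NRF2 targets (median −0.034) and the mitochondrially encoded mRNAs (median −0.24) changed direction, as did the medians of the Notch, glycolysis, lysosome, eicosanoid and fibro-adipogenic lists, called in neither fit. Hbb-bt ranged from −1.19 to 2.82 when single libraries were left out. Counts divided by 2 gave 3971 genes higher and 3772 lower. Dividing adds no sampling noise and nearly keeps the ratios between libraries, so this fit cannot show whether depth limits the calls. In simulated counts 58.2% of 1.5-fold and 60% of 2-fold changes were recovered.

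No pairing of the libraries by replicate number was seen. The deviations of same-numbered libraries from their group means correlated at −0.0035, −0.05 and 0.0089, and not every library correlated best with its own number. With 3 libraries per group, whose deviations sum to 0, these values cannot exclude a shared animal or day. With the replicate block, 4238 genes were higher and 4083 lower, more than the 3967 and 3749 of the main fit. Of these, 714 were at least 2-fold higher and 415 at least 2-fold lower. The fits shared 7656 calls in the same direction, and 8 lists were called with the block. Cdkn1a was called higher (0.13, adjusted p = 0.0428).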

Other observations

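In this part the tests of depth, of even counts, of the lists' percentiles and of other cells' markers, and all values with the length and GC trend removed, were chosen after the result was seen.

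Cytosolic ribosomal protein genes, a group picked after the data were seen, moved nearly as a whole. Of 85 measured genes 80 rose and 0 fell, with a median log2 fold change of 1.14 (camera p = 2.38e-26, unadjusted; p = 0.143 with an estimated correlation). Together they took 3.48 ± 0.205% of counts in controls and 7.03 ± 0.838% with EET (n = 3 each, exact permutation p = 0.1, the smallest possible). Their mRNAs are short, at a median of 887 bp, and with the length and GC trend removed 54 rose and 4 fell, at a median of 0.28.

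Other listed targets of the aryl hydrocarbon receptor moved less than Cyp1a1 did. Cyp1b1, another P450 induced through the aryl hydrocarbon receptor, rose by 0.58 ± 0.098 (adjusted p = 0.000193) and by 0.94 ± 0.08 with the length and GC trend removed; Ahrr, the receptor's repressor, was at 0.60 ± 0.32 (adjusted p = 0.135) and was called at 0.93 ± 0.31 with the trend removed (adjusted p = 0.0258). Tiparp, Cyp1a2 and Aldh3a1 did not pass in either fit. Ugt1a7c fell by 0.65 on the log2 scale (adjusted p = 0.0297), a call lost with the trend removed (adjusted p = 0.0672). Ugt1a6a was not among the genes tested.

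The pattern across all genes was that short mRNAs were higher and long mRNAs lower with EET. The tables argue against depth, since library totals overlapped (exact permutation p = 0.8) and EET 1, with the steepest fall along length, had a total within the range of the controls, and against GC content, since Spearman's rho with length was still −0.65 with the GC trend removed. A length-dependent difference between library preparations stays open: slopes along length differed within a group by up to 0.16 log2 units per doubling, while even counts, which depend on how mates were counted, were more frequent with EET by 3.14 percentage points among mRNAs over 3 kb and by 4.07 among those under 1.5 kb, and so not more among long mRNAs; by the median transcript length the difference over 3 kb was 2.20 points and the groups overlapped (exact permutation p = 0.7). It cannot be told apart from an effect of EET on mRNAs by length, because each slope group is also a treatment group. Of 7716 calls, 3290 had the same direction and were called with the trend removed, so a fold change of a very short or very long mRNA may say little about its own gene.

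Some gene groups stood apart beyond their length where genes were taken as independent, but not with an estimated correlation (adjusted p = 0.299 with the trend removed for the respiratory chain and for the extracellular matrix list). Among random lists matched on mRNA length and expression, the median of the respiratory chain lay at percentile 99.94 and that of the extracellular matrix list at 0.02. This argues against mRNA length, measured by the longest protein-coding transcript, as the whole cause of each. The length of the transcripts expressed in these cells was not measured, and the random lists take genes as independent. Lists not called as counted also lay far out, such as immediate early genes (0.08), macrophage markers (0.05) and red blood cell genes (0.06). Others lay inside their random range, such as the Notch (53.93) and cholesterol synthesis (42.07) lists. An extreme percentile is therefore not particular to the respiratory chain and matrix lists. The scavenging enzymes lay at 94.38, inside their random range. The ribosomal protein genes lay at 100, but they were picked because they rose in these libraries, so that value excludes nothing. How much of each change goes with length stays open: with the length and GC trend removed, the matrix median went from −0.47 to −0.24 ± 0.058 (bootstrap SE) and the respiratory chain median from 0.97 to 0.18 ± 0.058, where the matrix median passed the bound of −0.24 set before the corrected values were seen by less than its SE, and the respiratory chain median lay between its bounds. A lower share of other cells stays open for the matrix list, since 3 of 5 marker lists of other cell types had a median as low or lower with the trend removed (endothelial markers −0.43, at percentile 0 among matched lists) and the fibro-adipogenic and pericyte lists did not; an effect of EET itself was not told apart from this.

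Cyp1a1 was higher with EET with or without the length correction. Its log2 fold change was 2.02 with the length and GC trend removed, which argues against mRNA length, and ranged from 1.89 to 2.15 over all settings. A wider rise of aryl hydrocarbon receptor targets stays open, as 3 of 7 measured targets rose with the trend removed and 0 fell, between the bounds set before that count was seen. That EET acts on this receptor in these cells is a hypothesis that was not tested here, and neither was a vehicle effect.

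The libraries can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. The real division gave 7716 called genes, 1101 of them at least 2-fold changed, and 8 called lists. In each case it was the 1 division with a count as large, and the highest of the others gave 0, 0 and 6. Every other division still called lists, from 1 to 6, without a called gene. Those divisions hold the treatments in unequal numbers, so they are not free of an EET difference. A list call by camera at the preset correlation is therefore weak evidence on its own.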
